A study of Rattus norvegicus with 146 samples.

How the data were processed

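RNA from 5 organs of female rats was measured by quantitative PCR: adrenal gland, kidney, liver, lung and spleen of the spontaneously hypertensive rat (SHR) and of the normotensive Wistar-Kyoto strain (WKY) at 8, 10, 12, 16 and 24 weeks of age. Per the labels, RNA was extracted with a column kit and reverse transcribed, the cDNA was pre-amplified for 12 cycles with primers for the assayed genes, and 30 cycles of qPCR with an intercalating dye followed on 2 microfluidic arrays of 96 samples by 96 assays. The primers spanned introns. Which sample or assay ran on which array, the rule that set the cycle threshold (Ct), the averaging of repeated assays and the quality filter are not given in the sources used here, so a difference between the arrays could not be examined.

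The 3 tables, each of 92 genes and 146 samples, were deposited as sheets of 1 workbook. The first held non-normalized Ct values, in which a lower value means more cDNA. Of its 13432 values 305 were missing (2.27%), 120 sat at a floor of exactly 2.5 cycles and the highest was 27.2. The second, which the authors call normalized, held log2-scale values with the sign turned so that a higher value means more RNA. They were rebuilt from the Ct table as minus the difference between the Ct and the median Ct of the sample, minus the median of the gene within its organ, with a largest difference of 0.275 (kidney) and a lowest correlation of 0.994 (liver). The exact set of genes behind the sample median is not given in the sources used here. Because the authors centred each gene on 0 within each organ, the deposited log2 values compare samples of 1 organ and not the level of a gene between organs. The third sheet, deposited under the name of a fold change, held the square of each normalized value (largest difference 1.56e-13 over 13127 cells), so it carried no sign and was not used. The main analysis used the normalized table, and the Ct table served for the checks and the other scalings.

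Samples were grouped by organ, strain and age as stated in their titles. Each group held 3 rats, except the spleen of WKY rats at 12 weeks with 2 and the liver of WKY rats at 12 weeks, for which the sample list holds none. The columns of the Ct and normalized tables write 23 weeks where the titles write 24, and these were taken as the 24-week samples. One SHR spleen sample of 16 weeks carries WKY in its strain field and SHR in its title, source name and description, and was grouped as SHR. For 3 WKY lung samples of 8 weeks the title and the source name give other replicate numbers, and the title was used. In the adrenal gland 2 WKY columns of 12 weeks share a header, so they were assigned to their group but not to a given animal. Genes were identified by the symbols of the tables. A reference list held 90 of them as written and 1 as a synonym (Plgf, for Pgf). Ilrn was not found in it and is printed as written. The first sheet writes Gja where the others write Gja1. No genome build or coordinates are given in the sources used here, so none are printed.

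The tests were fitted with limma 3.58.1 in R 4.3.3, with least squares for each gene over the samples that had a value. A gene was tested in an organ when every group used there had at least 2 values. One fit per organ estimated the mean of each strain-by-age group and shared the spread over all groups of that organ. From it came the difference SHR minus WKY averaged over the ages, the same difference at each age, a moderated F test of whether the strain difference was equal at all ages, and a moderated F test of whether the mean of both strains was equal at all ages. In the liver the 12-week samples entered the fit, but the contrasts ran over the 4 ages with both strains. All tests were two-sided, with Benjamini-Hochberg correction over the genes of an organ (and of an age, for tests at each age) and a threshold of 0.05. A fit over all 146 samples, with the animal as a random block (estimated correlation within animals 0.0768), tested for each of the 82 genes measurable in every organ whether the strain difference averaged over 8, 10, 16 and 24 weeks was equal in the 5 organs. Standard errors (SE) are those of limma, standard deviations (SD) are between samples of a strain over all ages, and a fold is the size of a difference taken out of the log2 scale, which assumes that each cycle doubles the product.

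Gene lists were tested with the fry function of limma, which asks whether the members move, on balance, in 1 direction, or in either direction (mixed). Members with a missing value in an organ were left out of this test there. Neither test compares a list with other genes. Of 25 lists (13 functional and 12 of cell types) 7 had at least 3 tested members in some organ: renin-angiotensin, catecholamine and adrenergic, cytokine and chemokine, innate immune and NF-kB signalling, steroid and mineralocorticoid, extracellular matrix, and intracellular signalling. The other 18 had too few panel genes for a test. The redox and nitric oxide, vasoactive peptide and metabolic lists held 1 panel gene each (Nox4, Npr1 and Cd36), as did the adrenal medulla (Th), smooth muscle (Acta2) and hepatocyte (Agt) lists. The ion transport, circadian and growth factor lists and those of adrenal cortex, leukocytes, endothelium, adipocytes, kidney tubule, lung epithelium, pancreas, erythroid and neural cells held none, so these cell types could not be followed.

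The groups, the tests, the lists, the other settings and the rule for naming genes were set before the data were examined. The rule names, per organ, up to 10 genes in each direction with the largest averaged strain difference among those past the threshold, up to 3 in each direction per age, up to 5 genes for the strain-by-age test, up to 6 for age, up to 10 for the difference between organs, every gene of 1 sign in at least 4 organs, and up to 4 called and 2 uncalled members per list. Not every gene or list that met the rule is described here, and the tests of the renin-angiotensin list are left out in every organ. Other genes named in the text were chosen after their values were seen. The other settings were Ct values centred on the sample median of the genes complete in an organ, Ct values minus the mean of the 3 reference genes of the panel (Gapdh, Actb and Rpl13a), Ct values as they are, only genes with a value in every sample, missing values set to the lowest of the gene, robust variance shrinkage with a trend, the replicate number as a block, 1 fit for all organs with the animal as a block, only the 2 groups compared, correction over all ages together, no animal block, no 12-week samples, no spleen sample with conflicting labels, and each sample or animal left out in turn. The square table could not serve as the intended fold change setting. Both settings that left out the 6 samples with a median Ct over 2 cycles from that of their organ, or the values at the Ct floor, were chosen after seeing the data. The fits were checked against the functions of limma and tested on simulated data with 1 log2 added to 1 strain: the averaged test recovered from 72% (spleen) to 94.5% (kidney) of the altered genes and called at most 2.14% of the unaltered ones, while the strain-by-age test recovered a 1 log2 change at 1 age in 3% (spleen) to 32% (liver). The simulated noise was drawn for each gene on its own, without deviations shared between genes, values at the floor or aberrant samples. The share of unaltered genes called may therefore be higher in the real data. The number of rats limits the precision of every value.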

Results

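The data comprised 92 transcripts, some of them linked to blood pressure control, inflammation or signalling, in 146 organ samples of 30 female rats. The SHR develops high blood pressure as it matures, and the WKY strain is its normotensive control. Per the series description, the ages followed the development of hypertension, so the comparisons asked which transcripts differed between the strains in each organ, whether that difference changed with age, and whether it differed between organs. There were 15 SHR samples per organ, and 15 WKY samples for the adrenal gland, kidney and lung, 12 for the liver and 14 for the spleen. All 5 organs were present for 27 of the rats. The median Ct of a sample depends on how much cDNA entered the reaction and on how strongly the panel genes are expressed. It had a median of 8.68 cycles in the lung, 9.88 in the spleen, 10.2 in the kidney, 10.5 in the adrenal gland and 10.8 in the liver. In 6 samples it lay over 2 cycles from that of their organ: 3 adrenal, 1 lung and 2 spleen samples.

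Of the transcripts with a known main organ, Th, Agt and Ace were highest where textbooks place them. Tyrosine hydroxylase (Th), the rate-limiting enzyme of catecholamine synthesis, was 10.61 ± 0.27 log2 units (SE) higher in the adrenal gland than in the spleen, the next organ. Angiotensinogen (Agt), the precursor of angiotensin made mainly by hepatocytes, was 6.54 ± 0.38 higher in the liver than in the adrenal gland, and the angiotensin converting enzyme (Ace) was 3.87 ± 0.15 higher in the lung than in the kidney. These levels were Ct values relative to the sample median, and limma with the animal as a block gave adjusted p of 6.02e-62 for Th, 2.86e-35 for Agt and 5.2e-55 for Ace. Dbh, Pnmt and Cyp11b1 were not in the panel.

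In the adrenal gland, the peptide neurotensin and the catecholamine enzyme Th were among the transcripts higher in SHR. Neurotensin (Nts) was 4.09-fold higher (2.03 ± 0.46 log2, SE, adjusted p = 0.00233), the NADPH oxidase Nox4 2.79-fold (1.48 ± 0.37, adjusted p = 0.00424) and Th 2.28-fold (1.19 ± 0.18, adjusted p = 1.96e-05), all of them higher at each of the 5 ages. Th averaged 0.38 ± 0.45 (SD, n = 15) in SHR and -0.81 ± 0.59 (n = 15) in WKY, relative to the median of the gene in the organ. The immediate early transcription factor Egr1 (1.14 ± 0.22), the B cell transcription factor Ebf1 (1.06 ± 0.27), the repressor Bcl6 (0.79 ± 0.21, higher at 3 of 5 ages), the oestrogen receptor Esr1 (0.75 ± 0.20), the G protein regulator Rgs1 (0.74 ± 0.25, 4 of 5 ages) and the calcium-binding S100a4 (0.73 ± 0.18) were higher as well. Ephx2, the soluble epoxide hydrolase that inactivates epoxides of arachidonic acid, was 25.6-fold lower in SHR (-4.68 ± 0.29, adjusted p = 3.07e-12, lower at 5 of 5 ages). The chemokine Ccl5 (-1.71 ± 0.23), the tendon transcription factor Scx (-1.67 ± 0.43, lower at 3 of 5 ages), the orexin receptor Hcrtr1 (-1.51 ± 0.33), the endothelial lipase Lipg (-1.33 ± 0.20), the AP-1 member Fosl1 (-1.17 ± 0.28), the cell cycle factor E2f1 (-0.98 ± 0.31), Psap (-0.69 ± 0.22) and Ptgr1 (-0.53 ± 0.15) were lower.

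Of 89 genes tested in the adrenal gland, 22 passed adjusted p 0.05 in limma, 13 higher and 9 lower in SHR, and 31 had an unadjusted p under 0.05. With the 3 reference genes as the baseline, all 3 at the Ct floor in 2 of 30 adrenal samples, 10 genes passed, 2 higher and 8 lower, all 10 of them among the 22. Nox4, Th, Egr1, Ebf1, Bcl6, Esr1, Rgs1, S100a4, Agtr1a and E2f1 then missed the threshold with the sign unchanged. Centred on the median of complete genes 33 passed, 11 higher and 22 lower, and with Ct values as they are 7, all of them lower, where Nts and Th missed the threshold. The call of Rgs1 also ended without any of 6 samples left out in turn.

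The angiotensin receptor Agtr1a was higher in SHR adrenal glands (0.62 ± 0.15), and Agt (1.32 ± 0.97) and Agtrap (0.46 ± 0.18) did not pass. With Ct values as they are Agtr1a turned in sign. Agt ranged widely in WKY adrenal glands, from -8.02 to 2.79 log2. The cytokine and chemokine list fell (adjusted p = 0.0162), with Ccl5 the member of 8 that passed, also when adjusted over the list alone, while Il10 (-1 ± 0.59) and Tnf (-0.96 ± 0.48) did not. Its test ran over the 6 members without missing values, and so left out Il10 and Il6 (0.59 ± 0.34, not past the threshold). The test missed the threshold with the reference genes, with Ct values as they are and without the 12-week samples. In the catecholamine list Th was the member of 4 that passed, beside Adrb1 (-0.63 ± 0.47) and Adra1d (-0.22 ± 0.19), and the list test gave an adjusted p of 0.311. The intracellular signalling list held Egr1, higher, and Fosl1, lower, among 6 members (adjusted p = 0.8). No member of the innate immune list (6 tested, adjusted p = 0.311) or of the extracellular matrix list (4 tested, adjusted p = 0.27) passed.

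At 8 weeks 24 genes differed in the adrenal gland, 17 higher and 7 lower in SHR. The matrix protein Thbs1 (2.61 ± 0.47, adjusted p = 0.000501), Egr1 (2.37 ± 0.50, adjusted p = 0.00124) and Bcl6 (2.36 ± 0.47, adjusted p = 0.000855) were highest relative to WKY, and Scx (-5.15 ± 0.94, adjusted p = 0.000501), Ephx2 (-4.63 ± 0.64) and the adrenergic receptor Adra1d (-1.81 ± 0.42) lowest. At 10 weeks Ephx2 (-5.86 ± 0.64) and Ccl5 (-2.01 ± 0.51) were lower. At 12 weeks Th (1.5 ± 0.41) was higher, and Ephx2 (-5.29 ± 0.64) and Ccl5 (-2.34 ± 0.51) were lower. Ephx2 was lower at 16 weeks (-3.96 ± 0.64) and at 24 weeks (-3.65 ± 0.64), and Lipg at 24 weeks (-2.11 ± 0.45, adjusted p = 0.0049). In all, 33 gene-by-age pairs passed in 25 genes, 19 higher and 14 lower. Whether the strain difference changed with age passed for 0 genes in limma, with 10 at unadjusted p under 0.05, so the fall from 24 calls to 2 or 3 at later ages was not shown to be a change with age. Without WKY rat 2 of 8 weeks 10 genes passed at that age and 19 pairs in all, without WKY rat 1 of 12 weeks 13 genes passed at 12 weeks and 46 pairs in all, and without SHR rat 1 of 12 weeks 1 gene passed at 12 weeks. Without SHR rat 2 of 10 weeks 1 passed at 10 weeks, without SHR rat 3 of 10 weeks 4 at 16 weeks, without SHR rat 1 of 24 weeks 4 at 24 weeks, and without SHR rat 3 of 12 weeks the strain difference of 5 genes changed with age. The reference gene baseline, with all 3 genes at the Ct floor in WKY rat 3 of 8 weeks and WKY rat 3 of 24 weeks, gave 5 calls at 8 weeks. Ct values as they are gave 2, and leaving out the samples of aberrant median Ct, both of these rats among them, gave 31. Over all ages 11 pairs passed with the reference genes, 5 with Ct values as they are and 13 in fits of only the 2 groups compared, and with all organs in 1 fit the strain difference of 9 genes changed with age. The 12-week Th, 10-week Ccl5 and 12-week Ccl5 calls ended without any of 5, 4 and 2 samples left out in turn.

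In the kidney, Ephx2 was 23.2-fold lower in SHR (-4.54 ± 0.21 log2, SE, adjusted p = 4.44e-15), Agt 3.48-fold (-1.80 ± 0.30, adjusted p = 6.78e-05), the fatty acid transporter Cd36 3.37-fold (-1.75 ± 0.25, adjusted p = 7.83e-06) and Ace 2.91-fold (-1.54 ± 0.15, adjusted p = 2.13e-08), each at 5 of 5 ages. Ace averaged -0.68 ± 0.50 (SD, n = 15) in SHR and 0.87 ± 0.45 (n = 15) in WKY. The cyclin-dependent kinase inhibitor Cdkn1a (-1.92 ± 0.35, 12 SHR values, lower at 4 of 5 ages), arginase Arg1 (-1.21 ± 0.16, adjusted p = 5.1e-06) and the lysosomal protease Ctsl (-0.39 ± 0.14) were also lower. Higher in SHR were Rgs1 (0.91 ± 0.28), the monooxygenase Fmo2 (0.83 ± 0.16, adjusted p = 0.000306), the angiotensin receptor-associated protein Agtrap (0.69 ± 0.16), the integrin Itga5 (0.58 ± 0.11), Egr1 (0.51 ± 0.17), the natriuretic peptide receptor Npr1 (0.47 ± 0.13), the thrombin receptor F2r (0.46 ± 0.16), the deacetylase Sirt1 (0.41 ± 0.14) and the adrenergic receptor Adrb1 (0.35 ± 0.11).

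Of 89 genes tested in the kidney 21 passed, 14 higher and 7 lower, with 36 at unadjusted p under 0.05. With the reference genes 12 passed, 4 higher and 8 lower, 11 of them among the 21, and Rgs1, Egr1, Npr1, F2r, Sirt1 and Adrb1 missed the threshold with the same sign. Centred on the median of complete genes 11 passed, 5 higher and 6 lower, all among the 21, with Ct values as they are 7, all lower, and with all organs in 1 fit 11. The calls of Egr1, F2r, Sirt1 and Ctsl ended without any of 10, 12, 8 and 22 samples left out in turn, and that of Rgs1 without WKY rat 3 of 10 weeks.

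Beside Agt and Ace, lower, and Agtrap, higher, the angiotensin receptor Agtr1a stood at 0.26 ± 0.13 in the kidney and did not pass. The intracellular signalling list rose (adjusted p = 0.013), with Egr1 the member of 6 that passed, beside Hif1a (0.26 ± 0.11) and Fosl1 (0.23 ± 0.13). Its test, over the 5 members without missing values, missed the threshold with the reference genes, with centring on complete genes, with Ct values as they are and without the 12-week samples. Of the catecholamine list Adrb1 passed among 3 (adjusted p of the list = 0.311). The cytokine and chemokine list and the innate immune list missed the threshold (adjusted p = 0.057 each), with none of 8 and none of 6 members past it and Tlr4 at 0.27 ± 0.11 and Stat3 at 0.22 ± 0.09. The extracellular matrix list gave an adjusted p of 0.181 with no member past the threshold.

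**Figure D1:**
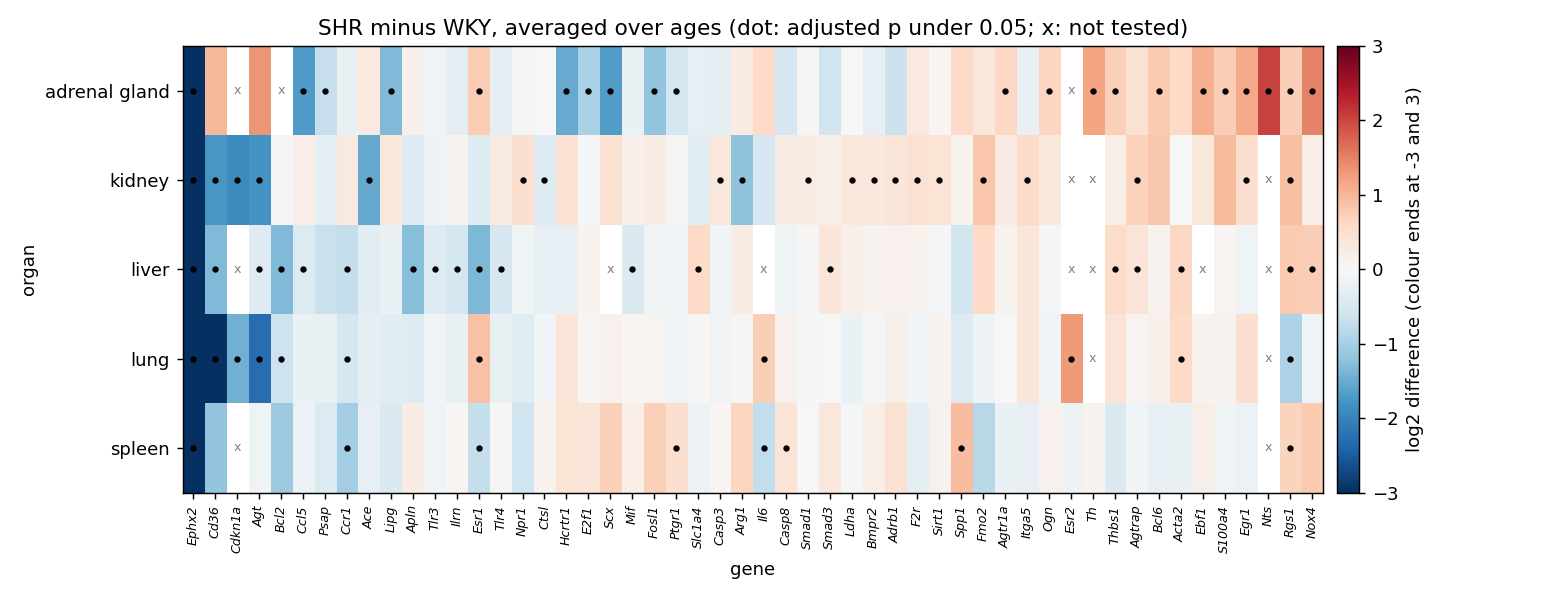
Log2 difference SHR minus WKY averaged over ages for genes that passed in at least 1 organ (horizontal axis) in each organ (vertical axis), with colours that end at -3 and 3, dots at adjusted p under 0.05 and crosses where a gene was not tested. Ephx2 carries a dot in all 5 organs, from -3.98 in the liver to -5.37 in the spleen, and Cd36 stands at -4.47 in the lung.

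The strain difference in the kidney changed with age for 14 genes, and all 14 were higher in SHR at 10 weeks. The leukotriene receptor Ltb4r was 2.70 log2 units higher in SHR at 10 weeks (SE 0.47) and stood at -0.90 at 8 weeks and -1.28 at 12 weeks (adjusted p of the change = 0.00142). Ilrn (1.29 at 10 weeks and -0.69 at 12 weeks, adjusted p = 0.0021), the vasoactive peptide Uts2 (2.39 and -0.85, adjusted p = 0.00285), the cytokine Il1b (1.33 and -0.88, adjusted p = 0.00285) and aromatase Cyp19a1 (3.03 and -1.32, adjusted p = 0.00316) followed. In limma 19 genes had an unadjusted p under 0.05. Leaving out 1 sample at a time gave from 11 to 17 genes, the reference gene baseline gave 8, all organs in 1 fit gave 6, and Ct values as they are gave 0. The WKY means were low at 10 weeks: Ltb4r averaged -1.92 ± 0.73 (SD, n = 3) in WKY and 0.77 ± 0.55 (n = 3) in SHR, and Cyp19a1 -2.20 ± 1.43 and 0.83 ± 0.42. These genes were weakly amplified: the median Ct of the 14 was 12.0 in the kidney, against 9.2 for the other genes tested.

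**Figure D2:**
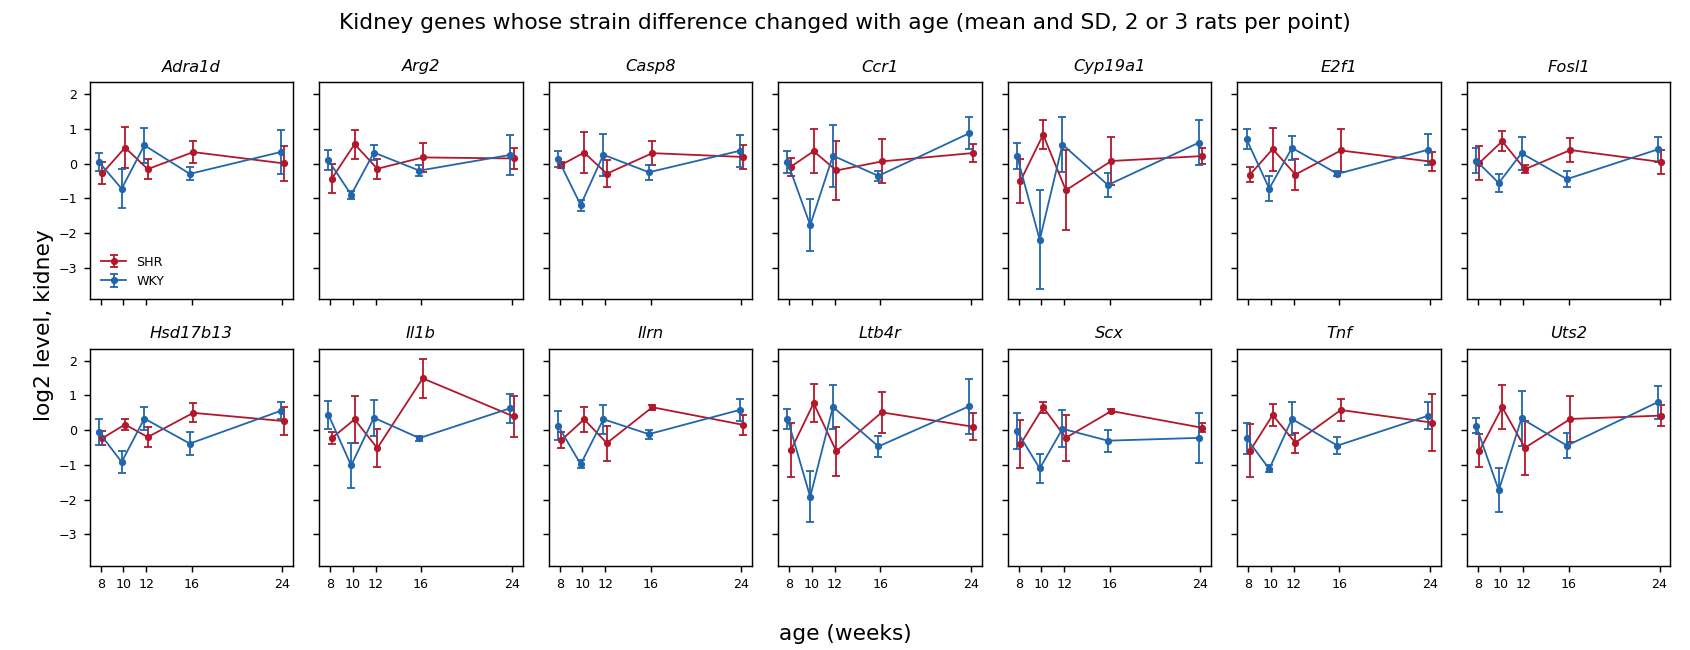
Kidney levels (vertical axis, log2 relative to the median of the gene) by age in weeks (horizontal axis) for the genes whose strain difference changed with age, as mean and SD of 2 or 3 rats per strain. The SHR mean lies above the WKY mean at 10 weeks in all 14 panels, by 2.70 for Ltb4r and 3.03 for Cyp19a1.

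At 10 weeks 22 kidney genes differed, 17 higher and 5 lower, led by Cyp19a1 (3.03 ± 0.58, adjusted p = 0.000609), Ltb4r (2.70 ± 0.47) and Uts2 (2.39 ± 0.44), with Ephx2 (-4.65 ± 0.47), Agt (-2.45 ± 0.67) and Cd36 (-2.40 ± 0.56) lowest. At 8 weeks 3 genes were lower: Ephx2 (-4.30 ± 0.47), Ace (-2.18 ± 0.34, adjusted p = 5.98e-05) and Arg1 (-1.53 ± 0.37). At 12 weeks Rgs1 (2.30 ± 0.60) and Fmo2 (1.41 ± 0.35) were higher, and Ephx2 (-3.85 ± 0.47) and Ace (-1.72 ± 0.34) lower. At 16 weeks 8 genes differed, among them Il1b (1.72 ± 0.39) and the lipid droplet enzyme Hsd17b13 (0.89 ± 0.26), higher, and Ephx2 (-5.31 ± 0.47), Cdkn1a (-2.94 ± 0.73) and Cd36 (-2.46 ± 0.56), lower. At 24 weeks 6 genes differed: Fmo2 was higher (1.22 ± 0.35), and Ephx2 (-4.57 ± 0.47), Cdkn1a (-3.93 ± 0.81) and Agt (-2.47 ± 0.67) were lowest. The total was 43 pairs in 26 genes, 22 higher and 21 lower, against 18 pairs with Ct values as they are and 23 with all organs in 1 fit. Left out singly, WKY rat 1 of 12 weeks raised the 12-week count from 4 to 11 and SHR rat 1 of 12 weeks lowered it to 2. WKY rat 3 of 16 weeks lowered the 16-week count to 5, and SHR rat 2 of 24 weeks lowered the 24-week count to 2, ending the Cdkn1a call. The 24-week Fmo2 call ended without any of 5 samples, the 8-week Arg1, 12-week Fmo2 and 16-week Hsd17b13 calls without any of 4, the 12-week Rgs1 and 24-week Agt calls without any of 3 and the 10-week Agt call without WKY rat 2 of 10 weeks.

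In the liver, Ephx2 was 15.8-fold lower in SHR (-3.98 ± 0.18 log2, SE, adjusted p = 6.07e-14). Esr1 (-1.36 ± 0.24, adjusted p = 0.000441), the apoptosis inhibitor Bcl2 (-1.33 ± 0.26), Cd36 (-1.32 ± 0.16, adjusted p = 3.8e-06), the peptide apelin Apln (-1.29 ± 0.37), the chemokine receptor Ccr1 (-0.71 ± 0.18), Ilrn (-0.53 ± 0.15, lower at 3 of 4 ages), the endotoxin receptor Tlr4 (-0.49 ± 0.13), the cytokine Mif (-0.43 ± 0.14) and Ccl5 (-0.41 ± 0.14, 3 of 4 ages) were lower. Cd36 averaged -0.28 ± 0.30 (SD, n = 15) in SHR and 1.05 ± 0.55 (n = 12) in WKY. Rgs1 (0.79 ± 0.27), Nox4 (0.74 ± 0.26), smooth muscle actin Acta2 (0.63 ± 0.22), the amino acid transporter Slc1a4 (0.57 ± 0.16), Thbs1 (0.55 ± 0.15), Agtrap (0.39 ± 0.10) and the TGF-beta effector Smad3 (0.36 ± 0.12) were higher.

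Of 84 genes tested in the liver 20 passed, 8 higher and 12 lower, with 26 at unadjusted p under 0.05. The count fell to 13 without SHR rat 3 or without WKY rat 3 of 16 weeks. Left out in turn, any of 15 samples ended the call of Rgs1, any of 19 that of Nox4, 20 that of Acta2, 10 that of Smad3, 12 that of Mif, 18 that of Ccl5 and 11 that of Tlr3. With the reference genes 19 passed, 5 higher and 14 lower, 17 of them among the 20, and Rgs1, Nox4 and Acta2 missed the threshold. With Ct values as they are 4 passed, all lower, and with all organs in 1 fit 12.

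No list passed in the liver. Agt (-0.38 ± 0.11) was lower, and Ace (-0.31 ± 0.28) and Agtr1a (0.12 ± 0.08) did not pass. Ccr1 and Ccl5 were lower among 7 cytokine and chemokine members (adjusted p = 0.375), and Tlr4 and Tlr3 (-0.38 ± 0.13) among 6 of the innate immune list (adjusted p = 0.311). Acta2 and Smad3 were higher among 4 extracellular matrix members (adjusted p = 0.27), where Spp1 stood at -0.54 ± 0.24. The catecholamine list (3 members, adjusted p = 0.949) and the intracellular signalling list (6 members, adjusted p = 0.8) held no gene past the threshold.

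At 8 weeks 10 liver genes differed, 8 of them higher, among them the chromatin protein Hmgb1 (0.87 ± 0.19) and the immunophilin Fkbp1a (0.80 ± 0.23), and Ephx2 (-4.35 ± 0.36) and Esr1 (-2.19 ± 0.49) were lower. At 10 weeks 4 genes differed, of which Ephx2 (-4.14 ± 0.36), Psap (-2.01 ± 0.52) and Cd36 (-1.22 ± 0.33) were lower. At 16 weeks 4 genes were lower, Ephx2 (-3.69 ± 0.36), Esr1 (-1.72 ± 0.49) and Cd36 (-1.58 ± 0.33) the most, and at 24 weeks 3: Ephx2 (-3.74 ± 0.36), Cd36 (-1.52 ± 0.33) and Ilrn (-1.18 ± 0.30). The total was 21 pairs in 14 genes, 9 higher and 12 lower, against 5 with Ct values as they are, 12 with all organs in 1 fit and 10 in fits of only the 2 groups compared. The strain difference changed with age for 3 genes (18 at unadjusted p under 0.05): Hmgb1 (0.87 at 8 weeks and -0.54 at 16 weeks, adjusted p = 0.0102), Agtr1a (0.70 and -0.40) and the nucleic acid-binding protein Cnbp (0.71 and -0.63, adjusted p = 0.0453 for both). Only 1 such gene passed with the reference genes, without the 12-week samples or with all organs in 1 fit, with Ct values as they are 0, and centring on complete genes ended the calls of Agtr1a and Cnbp. Leaving out 1 sample at a time gave 1 to 5 such genes, and the calls of Agtr1a and Cnbp ended without any of 16 and 18 samples. The 8-week count was 4 without SHR rat 3 of 8 weeks, the 10-week count 1 without WKY rat 1 of 10 weeks and the 16-week count 1 without WKY rat 1 of 16 weeks, which ended the 16-week Cd36 call. Without WKY rat 1 of 24 weeks the 24-week Cd36 call ended and the 16-week count was 7. The 16-week Esr1 call ended without any of 13 samples, 10-week Psap and Cd36 and 24-week Ilrn without any of 4, and 8-week Fkbp1a without any of 3.

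In the lung, Cd36 was 22.2-fold lower in SHR (-4.47 ± 0.21 log2, SE, adjusted p = 6.34e-15), Ephx2 17.2-fold (-4.10 ± 0.15, adjusted p = 2.71e-16) and Agt 4.84-fold (-2.27 ± 0.19, adjusted p = 6.82e-10), all at 5 of 5 ages. Cd36 averaged -2.08 ± 0.73 (SD, n = 15) in SHR and 2.39 ± 0.48 (n = 15) in WKY. Both oestrogen receptors were higher, Esr2 by 1.29 ± 0.20 (adjusted p = 3.09e-05) and Esr1 by 0.87 ± 0.23 (adjusted p = 0.00802), as were the cytokine Il6 (0.75 ± 0.17, 4 of 5 ages) and Acta2 (0.61 ± 0.19). Cdkn1a (-1.43 ± 0.20, adjusted p = 6.93e-06), Rgs1 (-0.92 ± 0.19), Bcl2 (-0.62 ± 0.20) and Ccr1 (-0.52 ± 0.13) were lower. Of 89 genes 11 passed in limma, 4 higher and 7 lower, with 21 at unadjusted p under 0.05. The calls of Acta2 and Bcl2 ended without any of 18 and 22 samples left out in turn, and Bcl2 missed the threshold with the reference genes, of which Actb sat at the Ct floor in 27 of 30 lung samples. With Ct values as they are 6 passed, 1 higher and 5 lower.

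The steroid list rose in the lung (adjusted p = 2.89e-05), with Esr2 and Esr1 past the threshold among 3 members (2 adjusted over the list alone) and Cyp19a1 at 0.06 ± 0.45, and missed the threshold with Ct values as they are. Beside Agt, lower, Ace (-0.27 ± 0.13) and Agtrap (0.08 ± 0.17) did not pass. The cytokine list held Il6, higher, and Ccr1, lower, among 8 (adjusted p = 0.27), and the extracellular matrix list Acta2 among 4 (adjusted p = 0.375). The innate immune list missed the threshold (adjusted p = 0.063) with no member of 6 past it, and the catecholamine (adjusted p = 0.352) and intracellular signalling lists (adjusted p = 0.27) held none.

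Cd36 and Ephx2 were lower in the lung at every age. Cd36 stood at -5.42 ± 0.47 at 8 weeks, -4.69 at 10, -4.17 at 12 and at 16, and -3.90 at 24 weeks, and Ephx2 between -4.64 and -3.18. Agt was lower at 8 (-2.80 ± 0.42), 10 (-2.40), 16 (-2.32) and 24 weeks (-2.63). Esr2 was higher at 10 weeks (1.83 ± 0.45, adjusted p = 0.0111) and Il6 at 16 weeks (1.41 ± 0.39, adjusted p = 0.024). Cdkn1a (-1.67 ± 0.45 at 16 and -1.75 ± 0.45 at 24 weeks) was lower. The total was 21 pairs in 8 genes, 2 higher and 19 lower (13 with Ct values as they are, 12 with all organs in 1 fit), with 6 genes at 8 weeks, 4 at 10, 2 at 12, 5 at 16 and 4 at 24. The strain difference changed with age for 0 genes in limma (2 at unadjusted p under 0.05). Without SHR rat 1 of 8 weeks 12 genes passed at 8 weeks, and without SHR rat 1 of 16 weeks 3 passed at 16 weeks. The 10-week Esr2 call ended without any of 3 samples left out and the 16-week Il6 call without any of 5.

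In the spleen, Ephx2 was 41.5-fold lower in SHR (-5.37 ± 0.38 log2, SE, adjusted p = 5.1e-10), and the matrix protein osteopontin (Spp1) was higher (0.93 ± 0.21, adjusted p = 0.00859), both at 5 of 5 ages. Ccr1 was lower (-1.05 ± 0.17, adjusted p = 0.000253) and averaged -0.73 ± 0.57 (SD, n = 15) in SHR and 0.30 ± 0.28 (n = 14) in WKY. Il6 (-0.73 ± 0.21, 4 of 5 ages) and Esr1 (-0.72 ± 0.22) were lower, and Rgs1 (0.66 ± 0.19), the prostaglandin reductase Ptgr1 (0.47 ± 0.13, 4 of 5 ages) and the apoptosis protease Casp8 (0.41 ± 0.12) were higher. At single ages Ephx2 alone passed, 5 of 5 times, between -6.49 ± 0.90 at 24 weeks and -3.80 ± 0.90 at 12 weeks. The strain difference changed with age for 0 genes in limma (2 at unadjusted p under 0.05).

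Of 89 genes 8 passed in the spleen, 4 higher and 4 lower, with 14 at unadjusted p under 0.05. Without both spleen samples of aberrant median Ct 41 genes passed and 20 pairs at single ages, and centring on complete genes gave 16 genes, 2 higher and 14 lower. Without the 12-week samples 5 passed and among genes with a value in every sample 1. The 5 pairs at single ages became 0 among those genes and 29 with all organs in 1 fit. With the reference genes, of which Actb sat at the Ct floor in 22 of 29 spleen samples, 6 passed, all lower and 4 of them among the 8, and Spp1, Rgs1, Ptgr1 and Casp8 missed the threshold. With Ct values as they are 2 passed, both lower, and Ptgr1 and Casp8 turned in sign. The count was 3 without SHR rat 2 of 16 weeks, SHR rat 1 of 24 weeks or any WKY rat among number 1 of 10 weeks, 2 and 3 of 12 weeks and 1 of 16 weeks, and 5 without SHR rat 2 of 8 weeks or WKY rat 1 of 24 weeks. Without SHR rat 1 or 3 of 24 weeks 16 pairs passed at single ages, 12 of them at 24 weeks without rat 1, and without SHR rat 3 of 10 weeks or SHR rat 1 of 12 weeks 8. The calls of Esr1, Casp8, Rgs1, Il6 and Ptgr1 ended without any of 20, 14, 8, 7 and 6 samples, and those of Esr1 and Casp8 without the sample of conflicting strain labels. The 12-week Ephx2 call ended without any of 17 samples.

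No list passed in the spleen. Ccr1 and Il6 were lower among 8 members of the cytokine list (adjusted p = 0.515), with Tnf at 0.34 ± 0.16, and Spp1 was higher among 4 of the extracellular matrix list (adjusted p = 0.27), with Smad3 at 0.35 ± 0.17. The catecholamine (adjusted p = 0.0882), innate immune (adjusted p = 0.8) and intracellular signalling lists (adjusted p = 0.8) held no gene past the threshold. Without the samples of aberrant median Ct the innate immune list turned upward and passed. For the steroid list, with Esr1 lower among 3, too few members were complete for a list test. Over the 5 organs 31 list-by-organ pairs were tested, 6 passed the test of 1 direction, not all of them described here, and 0 the mixed test. The reference genes gave 2 pairs, among them steroid in the lung. The fall of the cytokine list in the adrenal gland and the rise of the signalling list in the kidney then missed the threshold, and with Ct values as they are 0 pairs passed. Without WKY animal 3 of 8 weeks 10 pairs passed. The median, the mean and the test of the members differed in sign in 6 pairs, none of them among those that passed: catecholamine and signalling in the adrenal gland and in the liver, and signalling and steroid in the spleen.

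**Figure D3:**
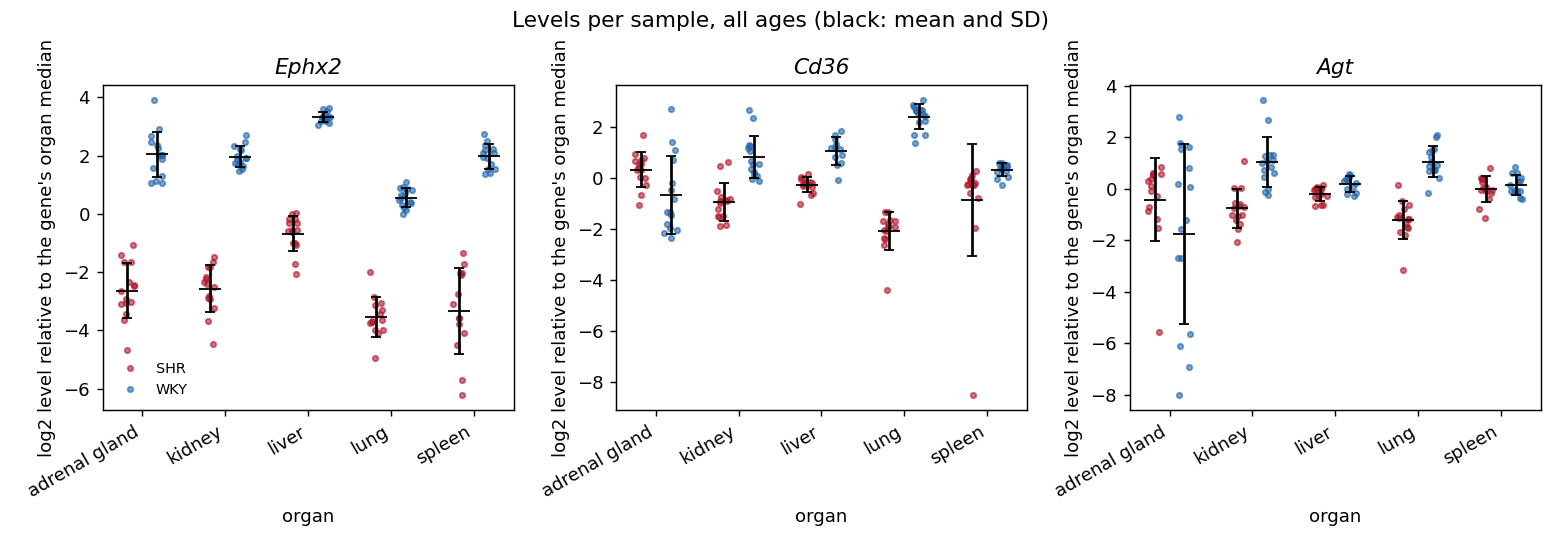
Levels per sample at all ages (vertical axis, log2 relative to the median of the gene in the organ) by organ (horizontal axis) for the named genes, with SHR and WKY side by side and black bars for mean and SD. The strains do not overlap for Ephx2 in any of the 5 organs, and Cd36 averages -2.08 in SHR and 2.39 in WKY lungs.

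Ephx2 was lower in SHR in all 5 organs, the 1 gene of the 82 tested everywhere that passed with 1 sign in each. Among 144 samples with a value (73 SHR and 71 WKY) the strains did not overlap in any organ. Rgs1, lower in the lung and higher in the other organs, was the other gene of 1 sign in at least 4 organs. Agt (kidney, liver and lung), Cd36 (kidney, liver and lung) and Ccr1 (liver, lung and spleen) were lower in 3 organs, a set chosen after the values were seen. In all, 45 genes passed in at least 1 organ, 32 of them in 1, and 37 in none. Many more genes passed in the spleen without its samples of aberrant median Ct, as given above. The number of organs in which a gene passed thus depends on the samples kept, and a call in 1 organ alone does not show a difference between organs. The Rgs1 calls in the adrenal gland, kidney, liver and spleen each ended without 1 or more single samples, as given above. Without any of 20 of the 30 animals the count of genes of 1 sign in at least 4 organs was 1. Among genes with a value in every sample, which leaves out Ephx2 in the lung and spleen, 0 genes had 1 sign in every organ, and with missing values set to the lowest 2 did.

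The size of the strain difference differed between organs for 29 of 82 genes (35 at unadjusted p under 0.05). A value given here for an organ need not have passed the averaged test of that organ. Cd36 stood at -4.55 ± 0.42 (SE) in the lung, -2.04 in the kidney, -1.46 in the spleen, -1.32 in the liver and 1.06 in the adrenal gland (adjusted p = 3.97e-12). In the limma fits of single organs Cd36 did not pass in the spleen (adjusted p = 0.233) or adrenal gland (0.138). In the spleen it stood at -3.38 at 24 weeks, where 1 SHR sample had an aberrant median Ct, and between -1.10 and -0.03 at other ages. Esr1 was at -1.36 ± 0.27 in the liver, -0.83 in the spleen and -0.76 in the kidney, against 0.82 in the adrenal gland and 0.77 in the lung (adjusted p = 4.3e-08). Ace was at -1.5 ± 0.20 in the kidney and between -0.31 and 0.38 elsewhere (adjusted p = 1.1e-06). Ccr1 ran from -1.06 ± 0.18 in the spleen to 0.46 in the kidney (adjusted p = 2.34e-06), Arg1 from -1.24 in the kidney to 0.65 in the spleen, Rgs1 from -0.93 in the lung to 0.79 in the liver and Fmo2 from -1.03 in the spleen to 0.68 in the kidney (adjusted p = 0.000168 each). Spleen Fmo2 was also lowest at 24 weeks (-2.04). Lipg was at -1.38 ± 0.22 in the adrenal gland and 0.25 in the kidney (adjusted p = 0.000178), Fosl1 at -1.20 in the adrenal gland and 0.87 in the spleen (adjusted p = 0.000292), and Tlr4 at -0.49 in the liver and 0.31 in the kidney (adjusted p = 0.000418). Without SHR animal 3 of 24 weeks 44 genes passed, with Ct values as they are 11 and with only genes that had a value in every sample 16.

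In the kidney Apln fell by 1.37 log2 units between 8 and 24 weeks (SE 0.25, adjusted p = 0.00277), and it was the 1 gene called there (17 at unadjusted p under 0.05). Liver Tnf was lowest at 10 weeks (-0.85, adjusted p = 0.0077) and liver Il10 at 24 weeks (-0.86, adjusted p = 0.0182), and they were among the 3 genes called there (15 at unadjusted p under 0.05). In the adrenal gland Il10 was lowest at 10 weeks (-3.79) and Psap at 8 weeks (-1.18), with adjusted p = 0.0409 for both and 14 genes at unadjusted p under 0.05. At 10 weeks adrenal Il10 stood at -4.75 SHR minus WKY, so the low mean came mainly from the SHR rats. SHR rat 1 of that group had an aberrant median Ct (12.8). In the lung and the spleen limma called 0 genes (13 and 8 at unadjusted p under 0.05). The adrenal Il10 and Psap calls ended without any of 16 and 21 samples left out in turn, and the liver Il10 call without any of 4. In the kidney 7 genes passed without SHR rat 3 of 12 weeks, 6 without WKY rat 1 of 10 weeks and 3 without SHR rat 1 of 24 weeks, and in the lung 3 without SHR rat 1 of 8 weeks or SHR rat 2 of 16 weeks. The counts depended on the setting: with Ct values as they are they were 59 in the kidney and 0 in the adrenal gland and liver, with all organs in 1 fit 11 in the adrenal gland, 3 in the kidney, 0 in the liver and 4 in the spleen, and without the 12-week samples 0 in the adrenal gland, 5 in the kidney and 2 in the lung. The reference genes gave 2 in the kidney and 0 in the adrenal gland.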

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

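The adrenal pattern at 8 weeks and the pattern of Ephx2, Cd36 and Agt were picked out only after the results were seen, and the other counts and genes below by rules set before the data were examined. The reference gene counts and the tests of a shifted assay were also chosen after the results. For each of these other genes the test of a difference between ages or between organs put it past the threshold.

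In the kidney the strain difference changed with age for 14 genes, led by Ltb4r (adjusted p = 0.00142), Ilrn (0.0021), Uts2 and Il1b (0.00285 each) and Cyp19a1 (0.00316), and all 14 were higher in SHR at 10 weeks. Leaving out 1 of the 10-week samples at a time gave at least 11 such genes, which argues against 1 aberrant sample, while the reference genes gave 8 and Ct values as they are 0, so a part of the centring on the sample median is not excluded. A candidate explanation is a background signal shared by weakly amplified assays. The members moved together beyond random sets of genes in 3 of the 4 other organs (median correlation 0.702 in the adrenal gland, 0.470 in the liver and 0.905 in the lung). They did so in the kidney itself as well (0.690). In the spleen they did not (0.614, under the 95th percentile of 0.757). But random sets there already correlated at a median of 0.397, against 0.0939 in the adrenal gland, 0.309 in the liver and 0.193 in the lung. The spleen was thus least able to show a shared movement and does not count against a background. A technical and a biological source cannot be told apart. Among 100 splits with ages exchanged within strain, the real one included, 1 reached the real 14, and the highest other gave 13. This argues against chance, but the 13 of another split lies close to the real count, so chance is not excluded. A change of WKY kidneys at 10 weeks, which the design could show, stays open as untested.

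At 8 weeks 24 genes differed in the adrenal gland, against 2 or 3 at later ages. Without WKY rat 3, whose median Ct stood apart, 26 passed, which argues against that sample as the source, but without WKY rat 2 the count was 10, so 1 other sample may carry much of it. The members as a set moved together beyond random sets in 0 of 4 other organs, which argues against a background shared by all of them. The set mixed 17 higher and 7 lower genes, which were not tested apart. Of its members 3 (Scx, Adra1d and Fosl1, all lower) were also among the weakly amplified kidney genes above. Those kidney genes moved together in the adrenal gland (0.702), so a background in a part of the set is not excluded. With the reference genes 5 passed, but all 3 sat at the Ct floor in WKY rat 3 of 8 weeks, 1 of the rats compared, so this count does not decide whether the centring on the sample median matters. That was not tested without this rat, and a strain difference confined to young adrenal glands stays open.

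Ephx2 differed between the strains by several log2 units in all 5 organs, Cd36 in the lung and Agt, by less, in the lung and kidney, which could come from a sequence variant under a primer rather than from RNA level. A variant that shifted Ct by 1 amount in every organ would give equal differences, and the highest adjusted p of the test between organs over 4 scalings was 0.012 for Ephx2, 7.42e-05 for Cd36 and 0.0249 for Agt, which argues against such an equal shift. The 4 scalings rest on the same Ct values and are not separate evidence. Ephx2 was lower by 3.98 to 5.77 log2 units in all organs. For Ephx2, Cd36 and Agt alike, a variant whose effect depends on the organ, or a shift added to a true difference, stays open as untested. A strain difference in transcription, splicing or RNA stability stays open as well.

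In the liver the strain difference changed with age for 3 genes: Hmgb1 (adjusted p = 0.0102), Agtr1a (0.0453) and Cnbp (0.0453). The count was 1 with the reference genes or without the 12-week samples and 0 with Ct values as they are. Of 100 splits, the real one included, 3 gave at least as many and the highest gave 12. So few splits argue against chance, but 1 gave 12, more than the real count, so chance is not excluded. The split with 12 may point to a structure among the samples, which was not tested.

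Between organs the strain difference differed for 29 genes. The adjusted p was 3.97e-12 for Cd36, 4.3e-08 for Esr1, 1.1e-06 for Ace, 2.34e-06 for Ccr1, 0.000168 for Arg1, for Rgs1 and for Fmo2, 0.000178 for Lipg, 0.000292 for Fosl1 and 0.000418 for Tlr4. With the strains of the animals exchanged within age, 1 of 100 splits, the real one, gave as many and the highest other gave 9. This argues against chance where no strain difference exists at all. The exchange removes every strain difference, so it does not test a strain difference of equal size in all organs.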

How the results depend on the processing

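Leaving out the samples of aberrant median Ct and leaving out the values at the Ct floor were chosen after seeing the data, and the other settings before the data were examined. Of 266 values 255 kept their direction and their side of the threshold with missing values set to the lowest and with robust variances, 236 with the median of complete genes, 211 with the reference genes and 133 with Ct values as they are. Leaving out 1 sample at a time kept 198 of 266, and leaving out the floor values 262 of 265. Correction over all ages together kept 73 of the 73 calls named at single ages. Dropping the animal block kept 10 of the 10 genes named for the difference between organs. The rule named the calls with the largest differences or the smallest adjusted p, so these tallies do not cover the other calls. Without the spleen sample of conflicting labels 65 of 67 kept theirs. The squared sheet could not be used, so that setting was not run. The number of rats per group limits the test of a change with age and the tests at single ages, and weakly amplified assays lie closest to the limit of detection. For all values below the cause was not tested, except where the setting itself removes genes or samples.

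Ct values as they are reversed Agtr1a in the adrenal gland (-0.0881), and Ptgr1 (-0.0491) and Casp8 (-0.34) in the spleen. Without the samples of aberrant median Ct, Stat3 (0.21) and Acta2 (0.43) in the spleen turned to higher in SHR, and the innate immune and NF-kB signalling list in spleen turned upward with an adjusted p of 0.0484, within a range of 0.00833 to 0.985 over all settings of that list.

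With the median of complete genes 1 gene changed strain difference with age in the adrenal gland, 11 differed in the kidney and 16 in the spleen averaged over ages, 9 pairs passed at single ages in the spleen and 10 list pairs passed. Calls were lost for Rgs1 in the adrenal gland and for Adrb1, Ctsl, Egr1, F2r, Rgs1 and Sirt1 in the kidney, Casp8 and Ptgr1 in the spleen, and the change with age of Agtr1a and Cnbp in the liver, beside the rise of the signalling list in the kidney. This scaling moved the median difference of all genes by -0.21 in the adrenal gland and -0.16 in the spleen. With the reference genes the averaged counts were 10 (adrenal gland) and 12 (kidney), the pairs at single ages 11 (adrenal gland), the changes of the strain difference with age 8 (kidney) and 1 (liver), the age counts 0 (adrenal gland) and 2 (kidney), the genes of 1 sign in at least 4 organs 1 and the list pairs 2. The median moved by -0.35 in the adrenal gland and -0.20 in the spleen. With Ct values as they are the averaged counts were 7 (adrenal gland), 7 (kidney), 4 (liver), 6 (lung) and 2 (spleen), the pairs at single ages 5, 18, 5 and 13 in the first 4 organs, the changes with age 0 (kidney and liver), the age counts 0 (adrenal gland and liver) and 59 (kidney), the genes that differed between organs 11, those of 1 sign in at least 4 organs 1 and the list pairs 0. The median moved by -0.71 in the adrenal gland, -0.19 in the kidney, -0.10 in the lung and -0.75 in the spleen.

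With only genes that had a value in every sample, which removes Ephx2 from some organs, the age count was 0 in the adrenal gland, the spleen held 1 gene averaged and 0 pairs at single ages, 16 genes differed between organs, and 0 genes had 1 sign in every organ or in at least 4. With missing values set to the lowest the age count was 0 in the adrenal gland, 8 pairs passed in the spleen and 2 genes had 1 sign in every organ. With robust variances the age counts were 1 (adrenal gland), 3 (kidney) and 1 (spleen), 8 pairs passed in the spleen and 1 gene had 1 sign in at least 4 organs.

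Without the 12-week samples the strain difference changed with age for 1 gene in the adrenal gland and 1 in the liver, the age counts were 0 (adrenal gland), 5 (kidney) and 2 (lung), 5 genes differed in the spleen and 1 gene had 1 sign in at least 4 organs. Calls averaged over ages were lost for Bcl6, E2f1, Psap and Rgs1 (adrenal gland), Egr1, F2r, Rgs1 and Sirt1 (kidney), Acta2, Ccl5 and Rgs1 (liver), Acta2 (lung) and Il6, Ptgr1 and Rgs1 (spleen), and for the cytokine list in the adrenal gland and the signalling list in the kidney. With all organs in 1 fit the averaged counts were 11 (kidney) and 12 (liver), the pairs at single ages 23 (kidney), 12 (liver), 12 (lung) and 29 (spleen), the changes with age 9 (adrenal gland), 6 (kidney) and 1 (liver), and the age counts 11 (adrenal gland), 3 (kidney), 0 (liver) and 4 (spleen). With only the 2 groups compared 13 pairs passed in the adrenal gland, 10 in the liver and 9 in the spleen, with 25 of the 73 calls named at single ages lost. Without the samples of aberrant median Ct 41 genes differed in the spleen, 20 pairs passed there at single ages, 1 gene changed with age in the spleen, the strain difference of 3 changed with age in the adrenal gland and 11 list pairs passed, while Rgs1 in the adrenal gland and Acta2, Bcl2 and the 16-week Il6 in the lung lost their calls.

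As a replicate block, the replicate number gave an age count of 0 in the adrenal gland, 13 genes averaged and 1 gene changing with age in the liver, and 1 gene of 1 sign in at least 4 organs. The labels do not say that the numbers pair the samples, and not every pair correlated: over 71 same-numbered pairs the correlation averaged 0.0885 (-0.817 to 0.778), 35 exceeded 0.1 and in 28 the own number correlated best. The kidney stood highest, with a mean of 0.365, 10 of 15 pairs over 0.1 and the own number best in 9, so a pairing there is not excluded.

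Leaving out 1 sample at a time gave, averaged over ages, 20 to 27 genes in the adrenal gland, 15 to 26 in the kidney, 13 to 20 in the liver, 9 to 12 in the lung and 3 to 11 in the spleen. Pairs at single ages ran from 19 to 46, 39 to 53, 16 to 26, 19 to 28 and 4 to 16, changes of the strain difference with age from 0 to 5, 11 to 17, 1 to 5, 0 to 0 and 0 to 1, and age counts from 0 to 3, 1 to 7, 2 to 4, 0 to 3 and 0 to 1, in the same order of organs. Leaving out 1 animal gave 22 to 44 genes that differed between organs, 1 to 1 of 1 sign in every organ, 1 to 3 in at least 4, and 6 to 10 list pairs.

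Each count was compared with 100 splits, the real one included, with strains exchanged within age or ages within strain. For the averaged difference 1 split reached the real count in the adrenal gland (22, highest other 8), kidney (21, 11), liver (20, 4) and spleen (8, 1), and 2 in the lung (11, 14). At single ages 1 split did in each organ (33 and 19, 43 and 24, 21 and 9, 21 and 12, 5 and 3). These counts argue against chance. In the lung 1 other split gave more averaged calls (14) than the real 11, so chance is not excluded there. The 1 gene of 1 sign in every organ (highest other 0), the 2 in at least 4 (1) and the 6 list pairs (2) were each reached by 1 split. For age few splits reached the real count in the adrenal gland (1 split, 2 genes, highest other 1) and liver (2 splits, 3 genes, highest other 8). These do not exclude chance. In the kidney 7 splits reached the real 1 and the highest gave 4, which gives no evidence against chance. All 100 splits reached the real 0 for age in the lung (highest other 1) and spleen (6), and for the change of the strain difference with age in the adrenal gland (18), lung (1) and spleen (3). The splits with several times the real count for age in the kidney and liver, and those with many genes where the real count was 0, may point to a structure among the samples, which was not tested.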

Other observations

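The levels between organs were read only after the values were seen, and so were the pair of like assays and the samples with aberrant medians. Beyond the transcripts named in the report, arginase (Arg1), an enzyme of the urea cycle, was 7.54 log2 units higher in the liver than in the kidney, the next organ, and the lipid droplet enzyme Hsd17b13 was 5.56 higher in the liver than in its next organ. Il6 was 6.51 higher in the spleen than in the lung, and the costimulatory molecule Cd86, found on antigen-presenting cells, was 3.60 higher in the spleen than in its next organ. Nox4, first described as a renal oxidase, was 3.21 higher in the kidney than in the lung, and Esr2 was 3.45 higher in the lung than in the spleen. Apln was highest in the lung (2.86), and Gja1 (2.76) and Npr1 (2.32) in the adrenal gland.

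Several samples stood apart in their median Ct. The median Ct was 7.57 in WKY rat 3 of 8 weeks, 6.08 in WKY rat 3 of 24 weeks and 12.8 in SHR rat 1 of 10 weeks among the adrenal glands, 12.1 in SHR rat 3 of 16 weeks among the lungs, and 12.1 in SHR rat 3 of 10 weeks and 13.3 in SHR rat 2 of 24 weeks among the spleens, the last with 25 values missing. Missing values numbered 31 in the adrenal gland, 50 in the kidney, 108 in the liver, 37 in the lung and 79 in the spleen. Actb, a reference gene, sat at the Ct floor in 27 of 30 lung and 22 of 29 spleen samples, Hspd1 in 20 of 30 and Spp1 in 13 of 30 adrenal samples.

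The spleen sample with SHR and WKY among its labels had an Ephx2 level of -2.02. The SHR spleens ranged from -6.23 to -1.36 and the WKY spleens from 1.36 to 2.73. It was kept in the SHR group, as its title states.

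The assays for Itpr1 and Ephb1 gave nearly equal Ct values over 144 samples, with a mean absolute difference of 0.123 cycles and a correlation of 0.994. The difference varied with an SD of 0.138, against 0.321 for the next closest pair, Rela and Rhoa. The normalized values of Itpr1 and Ephb1 correlated at 0.893.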
